A study of Homo sapiens with 6 samples.

How the data were processed

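RNA was sequenced from HCT116 cells with Cas9 and 1 of 6 sgRNAs, 2 against EIF5A, 2 against DOHH and 2 non-targeting. Per the labels' protocols, cells were lysed after 6 days in puromycin, RNA was purified with Direct-zol columns, libraries were made with the TruSeq Stranded Total RNA kit, and 75 bp single reads were sequenced on an Illumina NextSeq. Per the submitters' processing notes, reads were aligned with HISAT2 to GRCh38 and counted per transcript with featureCounts 1.6.0. The deposited values are raw counts of reads per transcript, made by the authors with featureCounts and not normalised or filtered. Counting options, the strand setting and the annotation release were not given in the sources used here. Ribosome profiling data of the series were not analysed here.

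The table held 58440 transcripts and 1 column per library. Of these 58404 matched GENCODE release 29 without the version suffix and 58072 with it, and 36 did not match, which held 0.0038% to 0.0045% of counts. Nearly all genes had a single transcript, and 124 genes had more than 1. In 99.1% of matched transcripts it was the one with the longest genomic span of its gene. If reads were counted on that model alone, reads outside it were missed, but the sources used here do not say how this transcript was chosen. No count was above 0 in any library for 24655 transcripts. Totals ranged from 35025427 to 46740565 counts, so that 3 counts were 0.0642 to 0.0857 CPM. Intervals cover the spread between libraries as modelled, and reads without molecular identifiers are not independent molecules.

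Counts were analysed in R 4.3.3 with edgeR 4.0.16. Transcripts passing filterByExpr by group (17516, 12970 of them protein-coding) were scaled by TMM, with factors of 1.01 and 1.01 (EIF5A), 1.08 and 1.06 (DOHH) and 0.889 and 0.959 (non-targeting). All 6 libraries entered a single fit with group means (estimateDisp, robust glmQLFit, glmQLFTest), with 3 residual degrees of freedom, a common dispersion of 0.0126 and a median of 9.58 prior degrees of freedom. The comparisons were EIF5A against non-targeting, DOHH against non-targeting, EIF5A against DOHH, and the mean of both targeted groups against non-targeting. P-values were adjusted by Benjamini-Hochberg over all tested transcripts, and a change was called at adjusted p under 0.05. The standard error is the log2 fold change divided by the root of the F statistic and is approximate. Fit and thresholds were checked on simulated data for EIF5A against non-targeting, in which 66 of 70 genes changed 2-fold, 30 of 70 changed 1.5-fold and 60 of 60 changed 4-fold were called, with 6 false calls. The changed genes had a mean of at least 50 counts and all groups had the same spread. These rates therefore do not cover weaker transcripts or controls that vary more than the targeted groups.

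Before the data were examined, 35 gene lists were fixed. They cover ATF4 targets, the unfolded protein response, p53 targets, polyamine synthesis and hypusination, ribosomal proteins of both subunits, ribosome biogenesis, translation initiation, elongation and rescue, nonsense-mediated decay, snoRNA hosts, tRNA synthetases, cholesterol synthesis, DNA replication, mitosis, histones, the respiratory chain, mitochondrially encoded mRNAs, mitochondrial ribosomal proteins, the proteasome, chaperones, lysosome and autophagy, interferon-stimulated, NF-kB, immediate early, NRF2, hypoxia, Wnt, epithelial-mesenchymal and collagen genes, and markers of intestinal, leukocyte, fibroblast, endothelial and embryonic kidney or neural cells. The 32 lists with at least 5 tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over lists within a comparison. Camera compares a list's genes with all others. Where the genes of a list vary together by more than the preset correlation, its p-values can be too small. It was repeated with the correlation estimated for each list from the residuals, which leaves 3 degrees of freedom, and beside fry, which tests whether a list's genes move on balance in a single direction, or, in its mixed form, change in either direction.

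Named genes followed a rule fixed before the data were examined. It took EIF5A, DOHH, EIF5A2, DHPS, MYC, ATF4 and CDKN1A always. Against non-targeting it took the 8 largest rises and 8 largest falls with adjusted p under 0.05, a mean log2 CPM of at least 3, both targeted libraries on the same side of both controls and a gene name, and for EIF5A against DOHH the 5 largest of each. From each called list it took the 3 members with the smallest adjusted p. Some genes that met the rule are not reported here. Exons of 7 of the 38 genes outside the list part overlap a gene on the opposite strand and those of 5 a gene on the same strand, which makes their counts less certain, as do near copies of HSPA1A, histones, ribosomal proteins, EIF5A and mitochondrial genes.

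Alternatives planned before the data were examined were DESeq2 1.42.0, limma-voom, RLE scaling, library totals without a scaling factor, no low-count filter, a mean of at least 50 counts, only the 4 libraries of the compared groups, the replicate number as a block, each library left out in turn, an added 2-fold minimum, and both other list tests. An offset for GC content and transcript length, leaving out mitochondrial and small noncoding RNAs before scaling, and separate controls for each response were added after the data were seen. Groups of 2 libraries are too small to test single libraries as extreme values or to count other splits of the samples.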

Results

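HCT116 is an established human colon carcinoma cell line. Cells were infected with lentivirus carrying Cas9 and a single guide RNA (sgRNA) against EIF5A, against DOHH or against no human target, and were selected in puromycin for 6 days. EIF5A encodes the translation factor eIF5A, which binds stalled ribosomes and carries hypusine, a modified lysine made from spermidine. DOHH encodes the hydroxylase that completes hypusine. The series concerns ribosome pausing and the choice of start codons, and the RNA libraries analysed here give the transcript levels in these cells. Each target and the non-targeting control had 2 sgRNAs, and each sgRNA gave 1 library of 75 bp reads, so that 3 groups of 2 libraries were compared. The libraries held 40208502 and 45051757 counted reads with EIF5A sgRNAs, 46740565 and 43429842 with DOHH sgRNAs and 35025427 and 36803668 with non-targeting sgRNAs. The labels do not say that the sgRNAs of a group were grown as separate cultures, so p-values measure only the spread between these samples. That spread was pooled over the 3 groups, although the non-targeting libraries varied most, so p-values against controls can be too small. Changes are log2 fold changes ± standard error with 2 libraries per group. Adjusted p-values of genes are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 17516 transcripts.

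The targeted genes were examined first. EIF5A (counted transcript ENST00000336452, 6 exons, chromosome 17, 7306999 to 7312463, plus strand, GRCh38) had 287 and 307 CPM (counts scaled to library size) with EIF5A sgRNAs. It had 633 and 652 CPM with DOHH sgRNAs and 734 and 878 with non-targeting sgRNAs. It was 2.72-fold lower in EIF5A-targeted cells than in controls (log2 fold change -1.44 ± 0.13, 95% interval -1.73 to -1.15, adjusted p = 4.33e-05). It was not called in DOHH-targeted cells (-0.33 ± 0.13, adjusted p = 0.0668), but was called without the first non-targeting library (-0.45, adjusted p = 0.00285), at a mean of at least 50 counts (0.0388) and with an offset for GC content and length (0.0138). The counts can include reads of processed pseudogenes and of GPS2, a gene on the opposite strand with an exon that overlaps EIF5A. DOHH (ENST00000427575, 5 exons, chromosome 19, 3490822 to 3500940, minus strand) was weakly expressed, with 7.03 and 8.12 CPM with EIF5A sgRNAs, 6.54 and 3.92 with DOHH sgRNAs and 3.89 and 7.37 with non-targeting sgRNAs. A difference between DOHH-targeted cells and controls was not detectable against the spread within groups, at 121 to 368 counts per library (-0.11 ± 0.28, interval -0.72 to 0.50, adjusted p = 0.781). With EIF5A sgRNAs DOHH was at 0.42 ± 0.28 (adjusted p = 0.253), or 0.97 without the second non-targeting library (adjusted p = 0.0147). The transcript level therefore did not check the DOHH labels. The sgRNA sequences and their positions were not given in the sources used here.

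The non-targeting libraries stood apart from the 4 targeted libraries in RNA composition. RN7SL, the noncoding RNA of the signal recognition particle, took 10.01% and 7.96% of counts in the non-targeting libraries and 4.27% to 4.83% in the targeted libraries. Mitochondrially encoded mRNAs took 5.21% and 2.96% against 1.10% to 1.49%, and mitochondrial rRNAs 1.49% and 0.612% against 0.201% to 0.323%. The 10 most counted transcripts took 18.6% and 13.3% of the non-targeting libraries and 8.11% to 9.12% of the others. The non-targeting libraries also differed most from each other, with a chi-square of 77.8 per degree of freedom against 20.04 for EIF5A and 10.6 for DOHH. The leading principal component (60.2% of the variance) separated them from the targeted libraries. The labels give no batch for these libraries, so such a difference and the targeting cannot be told apart.

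**Figure D1:**
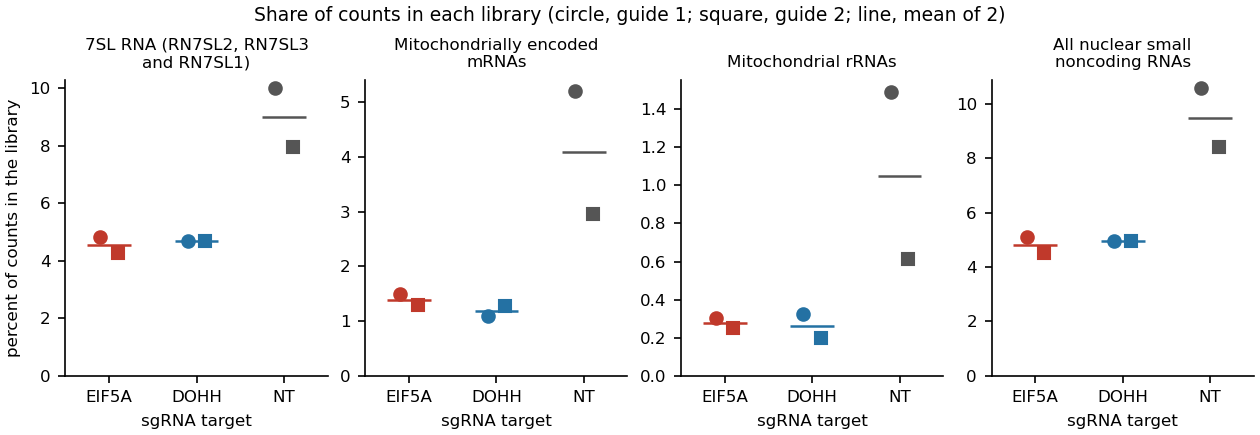
Percent of counted reads taken by RN7SL, mitochondrially encoded mRNAs, mitochondrial rRNAs and all nuclear small noncoding RNAs in each of the 6 libraries (points), with the mean of each group (lines). Both non-targeting (NT) libraries lie above the 4 targeted libraries in each class, with RN7SL means of 8.98% (NT), 4.55% (EIF5A) and 4.69% (DOHH).

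The comparison of EIF5A sgRNAs with non-targeting sgRNAs asks how transcript levels change when the gene of the factor is targeted. CXXC1, which encodes a reader of unmethylated CpG sites, rose 9.68-fold (3.28 ± 0.13, adjusted p = 9.88e-08). CHAC1, a glutathione-degrading enzyme and ATF4 target, rose 4.45-fold (2.15 ± 0.15, adjusted p = 1.23e-05). The co-chaperone gene BAG1 fell (-2.33 ± 0.14, adjusted p = 7.2e-06), as did mitochondrially encoded transcripts such as MT-ND3 (-1.99 ± 0.23, adjusted p = 1.22e-04). By camera with a preset correlation, ATF4 targets (26 of 36 rose), interferon-stimulated (27 of 33), lysosome (28 of 38) and proteasome genes (20 of 31) were among the lists called higher. Mitochondrial mRNAs (13 of 13 fell) and the list of small nucleolar RNA (snoRNA) hosts (14 of 23) were called lower, and for these 6 lists adjusted p = 0.508 to 0.635 with an estimated correlation.

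In all, 3371 transcripts rose and 3162 fell (6533 of 17516), of which 875 rose and 1164 fell at least 2-fold. Among the 8 largest rises that met the rule for named genes were CXXC1, CXCL8, IFI6, BIRC3, ARRDC4, WWC3 and CHAC1, between 2.15 and 3.28. The 8 largest falls under this rule were MT-RNR1, BAG1, CAV2, MT-ATP6, MT-RNR2, MT-ND3, KIAA1191 and MT-CO2, between -2.65 and -1.90. For each of these, both targeted libraries lay on the same side of both controls, because the rule requires it. The call of the chemokine gene CXCL8 (3.01 ± 0.57, adjusted p = 0.00971) ended without the first or second non-targeting library (3.40 and 2.70) and with no low-count filter (3.03, adjusted p = 0.118). The call of the interferon-induced IFI6 (2.82 ± 0.37, adjusted p = 4.01e-04) also ended without the first or second non-targeting library (2.49 and 3.27). The mitochondrial rRNAs MT-RNR1 (-2.65 ± 0.53, adjusted p = 0.014) and MT-RNR2 (-1.99 ± 0.39, adjusted p = 0.00435) were not called without the first non-targeting library (-1.73, adjusted p = 0.0642, and -1.14, adjusted p = 0.0672) or with no low-count filter (0.131 and 0.19). MT-RNR1 was also not called without the second EIF5A library (adjusted p = 0.0716), and MT-ATP6 was at -1.32 without the first non-targeting library. The counted CAV2 model covered 26.0% of the length of its longest transcript.

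Among 36 measured ATF4 targets of the integrated stress response, 26 rose and 3 fell (26 and 3 adjusted over the list alone), with a median of 0.85. This list had camera adjusted p = 4.74e-07, and adjusted p = 0.508 with an estimated correlation. Examples were the cystine transporter gene SLC7A11 (1.79 ± 0.13) and the transcription factor genes ATF3 (1.67 ± 0.17) and DDIT3 (1.44 ± 0.15), while XPOT, a tRNA exporter, fell (-1.02 ± 0.13). The ATF4 transcript itself was not called (0.26 ± 0.12, adjusted p = 0.11), except without the first non-targeting library (0.30, adjusted p = 0.0413) and without a scaling factor (0.39, adjusted p = 0.0264). Of 33 interferon-stimulated genes 27 rose and none fell (29 and 0 adjusted over the list alone, median 1.01), among them OAS3 (1.82 ± 0.21) and OASL (1.70 ± 0.19). Their camera adjusted p was 1.78e-09, and adjusted p = 0.508 with an estimated correlation. Of 20 NF-kB and inflammatory genes 14 rose (14 adjusted over the list alone, median 0.61), including BIRC3 (2.29 ± 0.22) and PTGS2 (1.66 ± 0.20). Of 28 immediate early genes 18 rose (18 adjusted over the list alone, median 0.76), including DUSP4 (1.65 ± 0.12) and JUN (1.64 ± 0.19). Adjusted p from camera was 1.59e-05 for NF-kB and 1.3e-05 for immediate early genes, and adjusted p = 0.606 with an estimated correlation for each. CDKN1A, which encodes the cell cycle inhibitor p21, rose (0.78 ± 0.15, adjusted p = 0.00178). Of 30 p53 targets 8 rose and 4 fell (8 and 4 adjusted over the list alone), and the list was not called (camera adjusted p = 0.337).

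Genes of protein turnover and folding also moved. Of 31 proteasome genes 20 rose and none fell (21 and 0 adjusted over the list alone), among them PSMC4 (1.42 ± 0.17) and PSMA2 (1.14 ± 0.14). The proteasome median was 0.54, or 0.35 and 0.87 without the first and the second non-targeting library (camera adjusted p = 1.3e-05, and adjusted p = 0.635 with an estimated correlation). Of 38 lysosome and autophagy genes 28 rose and 3 fell (29 and 3 adjusted over the list alone, median 0.60), with the protease gene CTSL at 1.89 ± 0.22 and the proton pump gene ATP6V1B2 at 1.11 ± 0.14. The lysosome list had camera adjusted p = 1.49e-05, and adjusted p = 0.606 with an estimated correlation. Of 29 genes of the unfolded protein response of the endoplasmic reticulum 17 rose and 1 fell (20 and 1 adjusted over the list alone), including ATF6 (0.84 ± 0.12) and XBP1 (0.80 ± 0.12). Their median was 0.48, or 0.29 without the first non-targeting library (camera adjusted p = 5.01e-04, and adjusted p = 0.606 with an estimated correlation). The 28 cytosolic heat shock chaperones were not called (3 rose and 2 fell, the same adjusted over the list alone, median 0.10, camera adjusted p = 0.906).

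Among translation genes, 15 of 23 cytosolic tRNA synthetases rose and 1 fell (15 and 1 adjusted over the list alone, median 0.48), led by SARS1 (1.52 ± 0.12) and CARS1 (1.10 ± 0.15). Of 44 initiation and start codon factors 19 rose and 3 fell (19 and 3 adjusted over the list alone, median 0.25), including EIF4A2 (0.96 ± 0.14) and EIF1 (0.93 ± 0.14), whose product guards start codon choice. For the synthetases camera adjusted p was 5.01e-04 and for initiation factors 0.00757, and adjusted p = 0.606 with an estimated correlation for each. Of 19 nonsense-mediated decay factors 10 rose (10 adjusted over the list alone, median 0.36), including SMG5 (1.18 ± 0.17). Of 23 snoRNA host and translation-sensitive long noncoding RNAs none rose and 14 fell (0 and 15 adjusted over the list alone, median -0.47), with SNHG4 at -1.71 ± 0.19 and SNHG15 at -1.22 ± 0.15. Decay factors had camera adjusted p = 0.00259 and snoRNA hosts 2.55e-04, and adjusted p = 0.606 with an estimated correlation for each. Of 64 ribosome biogenesis genes 19 rose and 1 fell (18 and 1 adjusted over the list alone), including NOC2L (1.32 ± 0.19). Their median was 0.20 (camera adjusted p = 0.00757, and adjusted p = 0.635 with an estimated correlation). It was 0.37 without the second non-targeting library, and the call ended without the first (0.09, adjusted p = 0.136). Ribosomal protein genes were not called, with 3 of 47 of the large subunit higher and 2 lower (2 and 2 adjusted over the list alone, median -0.06, camera adjusted p = 0.798). Of 31 of the small subunit 1 rose and 6 fell (0 and 1 adjusted over the list alone, median -0.09, camera adjusted p = 0.337), and without a scaling factor the medians were 0.07 and 0.05. Both subunits were called lower without the second non-targeting library (-0.25 and -0.23, adjusted p = 0.0121 and 0.0157).

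All 13 mitochondrially encoded mRNAs fell (13 adjusted over the list alone), in a comparison in which their mean share of counts was 1.39% against 4.09% in controls. Their median was -1.48, or -0.94 without the first non-targeting library (camera adjusted p = 1.3e-05, and adjusted p = 0.606 with an estimated correlation). Of 396 small noncoding RNAs encoded in the nucleus 264 fell and 7 rose (median -1.18). The nuclear-encoded respiratory chain had 31 of 73 genes higher and 4 lower (33 and 4 adjusted over the list alone), such as NDUFV1 (1.44 ± 0.21) and ATP5F1B (1.28 ± 0.18), while NDUFB9 fell (-0.94 ± 0.12). The respiratory chain median was 0.23, or 0.34 without the second non-targeting library (camera adjusted p = 0.00237, and adjusted p = 0.637 with an estimated correlation). Of 38 replication-dependent histone transcripts, which share sequence, 19 rose and 3 fell (19 and 3 adjusted over the list alone), among them H4C8 (1.57 ± 0.17). Their median was 0.50 (camera adjusted p = 0.00211, and adjusted p = 0.667 with an estimated correlation), or 0.26, 0.80 and 0.28 without the first and second non-targeting and the second EIF5A library. Of 32 hypoxia and glycolysis genes 14 rose (16 adjusted over the list alone, median 0.50), such as HK1 (1.06 ± 0.17). The hypoxia list had camera adjusted p = 0.00211, and adjusted p = 0.637 with an estimated correlation, and its call ended without the second EIF5A library (median 0.17, adjusted p = 0.0586).

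Of 15 Wnt target and colon progenitor genes 7 rose and 1 fell (8 and 1 adjusted over the list alone, median 0.41), including NOTUM (1.11 ± 0.16) and RNF43 (0.92 ± 0.12). Wnt targets had camera adjusted p = 0.00474, and adjusted p = 0.508 with an estimated correlation. Of 23 epithelial-mesenchymal genes 10 rose (10 adjusted over the list alone, median 0.42), including ITGA5 (1.34 ± 0.17). Their camera adjusted p was 0.00211, and adjusted p = 0.606 with an estimated correlation. Of 27 collagens and polyproline-rich matrix or actin regulators 14 rose and 4 fell (14 and 5 adjusted over the list alone, median 0.45), with VASP at 1.22 ± 0.16 and WASF1 at -1.04 ± 0.13. This list had camera adjusted p = 0.0148, and adjusted p = 0.635 with an estimated correlation, and its call ended without the first non-targeting library (0.0795) and at a mean of at least 50 counts (0.0882). As markers of other cells, all 5 measured fibroblast genes rose (5 adjusted over the list alone, median 0.99). The fibroblast list had camera adjusted p = 0.0108, and adjusted p = 0.606 with an estimated correlation. Its call by the preset camera ended with no low-count filter (median 0.78, adjusted p = 0.0537). Without the second EIF5A library FBLN1, PDGFRB and TAGLN were not called (0.66, 1.55 and 0.90, adjusted p = 0.0898, 0.169 and 0.0997), nor were PDGFRB and TAGLN without the second non-targeting library (1.42 and 1.22, adjusted p = 0.122 and 0.09) or PDGFRB with DESeq2 (0.0884). Of further markers 2 of 4 endothelial genes, 1 of 3 embryonic kidney and neural genes and none of 1 leukocyte gene rose (2, 3 and 0 adjusted over the list alone), too few members for a list test.

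Lists that were not called follow with their counts. Polyamine synthesis and hypusination had 5 of 19 genes higher and 5 lower, the targeted EIF5A among the lower (6 and 6 adjusted over the list alone, camera adjusted p = 0.557). Elongation and ribosome rescue had 7 of 26 higher and 1 lower, the same adjusted over the list alone, with a median of -0.03, a mean of 0.08 and an upward test (camera adjusted p = 0.508). Cholesterol synthesis had 2 of 28 higher and 11 lower (camera adjusted p = 0.117), DNA replication 13 of 50 higher and 5 lower (0.298) and differentiated intestinal genes 3 of 5 higher and 1 lower (0.312), each the same adjusted over the list alone. Cholesterol synthesis was called lower without the first non-targeting library (-0.32, adjusted p = 0.00325), the second EIF5A library (-0.25, 0.0249), at a mean of at least 50 counts (0.0368) and with the GC and length offset (0.0401). Replication was called higher without the first EIF5A library (0.0254), and mitochondrial ribosomal proteins without the second non-targeting library (0.24, 0.0063). Mitosis had 7 of 49 higher and 8 lower (6 and 7 adjusted over the list alone, median 0.00, mean -0.01, camera adjusted p = 0.841). Mitochondrial ribosomal proteins had 18 of 75 higher and 10 lower (19 and 10 adjusted over the list alone, camera adjusted p = 0.337). NRF2 antioxidant genes had 7 of 24 higher and 5 lower (8 and 6 adjusted over the list alone, median -0.09, mean 0.09, camera adjusted p = 0.841). EIF5A2 (-0.26 ± 0.12, adjusted p = 0.112), DHPS (0.37 ± 0.15, adjusted p = 0.0626) and MYC (0.20 ± 0.12, adjusted p = 0.218) were not called. Without the second non-targeting library EIF5A2 fell (-0.33, adjusted p = 0.0187) and DHPS rose (0.54, adjusted p = 0.00393), as DHPS did without a scaling factor (0.49, adjusted p = 0.0366) and with the replicate block (0.37, adjusted p = 0.0463).

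Without the second EIF5A library 3240 transcripts were called. Of all called transcripts 51.6% rose, against 65.6% without a scaling factor, where the median of all genes moved by 0.12 and those of ribosome biogenesis and the respiratory chain were 0.33 and 0.36, and 40.9% with an offset for GC content and length, where those of ribosome biogenesis, nonsense-mediated decay, Wnt targets and collagens were 0.07, 0.18, 0.17 and 0.25. With this offset the median of all genes was -0.10, so part of the lower list medians is a shift of all genes.

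**Figure D2:**
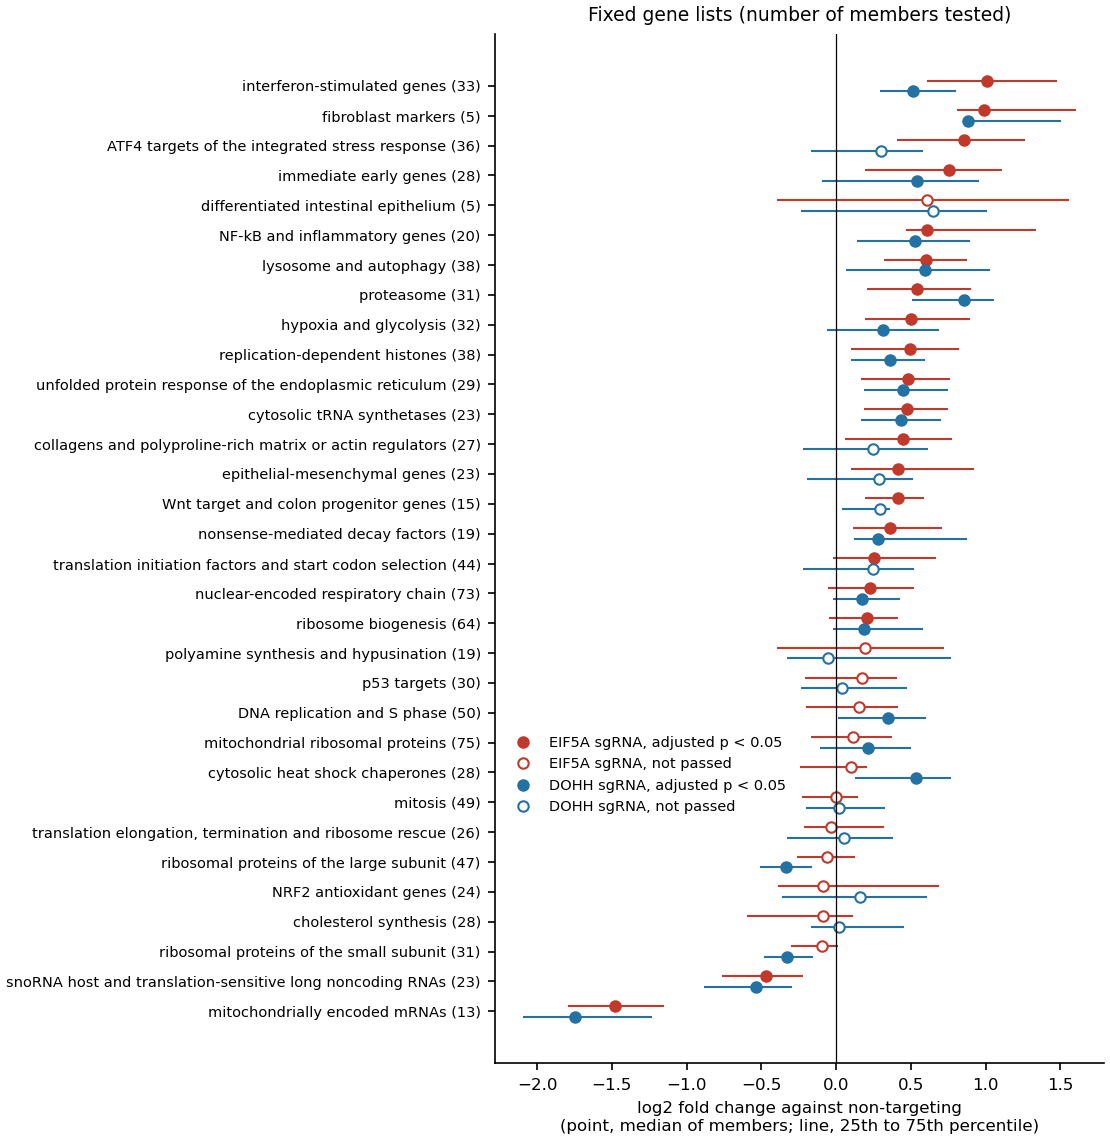
Median log2 fold change against non-targeting sgRNAs (points) of the members of each fixed gene list with at least 5 members tested, with lines from the 25th to the 75th percentile of members. Filled points passed camera at the threshold of 0.05, and mitochondrially encoded mRNAs lay lowest for both targets, at -1.48 (EIF5A) and -1.75 (DOHH).

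The comparison of DOHH sgRNAs with non-targeting sgRNAs asks how transcript levels change when the enzyme that completes hypusine is targeted. The fatty acid oxidation gene ACADVL rose 4.75-fold (2.25 ± 0.23, adjusted p = 1.14e-04) and CXXC1 rose 4.59-fold (2.20 ± 0.13, adjusted p = 9.26e-06). The protease gene CTSL rose 4.24-fold (2.08 ± 0.22, adjusted p = 1.16e-04) and FUBP1, which encodes a DNA- and RNA-binding regulator of MYC, rose 4.01-fold (2.00 ± 0.15, adjusted p = 2.49e-05). BAG1 fell (-2.26 ± 0.14, adjusted p = 9.62e-06), as did mitochondrially encoded mRNAs such as MT-CO2 (-2.43 ± 0.27, adjusted p = 1.38e-04). By camera with a preset correlation, proteasome (27 of 31 rose), chaperone (16 of 28), lysosome (22 of 38) and interferon-stimulated genes (15 of 33) were among the lists called higher. Large and small subunit ribosomal proteins (16 of 47 and 13 of 31 fell), mitochondrial mRNAs (13 of 13) and snoRNA hosts (14 of 23) were called lower, and for these 8 lists adjusted p = 0.66 to 0.667 with an estimated correlation.

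In all, 3437 transcripts rose and 3324 fell (6761 of 17516), of which 857 rose and 1053 fell at least 2-fold. Under the rule for named genes the 8 largest rises were ACADVL, IGSF8, CXXC1, CTSL, HSPBP1, H1-10, FUBP1 and AAMP, between 1.99 and 2.25, and the 8 largest falls MT-RNR1, MT-CO2, BAG1, MT-RNR2, MT-ATP6, MT-ND3, MT-CO1 and MT-CO3, between -2.46 and -2.04. An exon of the opposite-strand gene DLG4 overlaps ACADVL, and the strand setting of the counting was not given. MT-RNR1 (-2.46 ± 0.53, adjusted p = 0.017) was not called without the first non-targeting library (-1.54, adjusted p = 0.0822), where MT-RNR2 was at -1.36, and with no low-count filter neither was called (0.151 and 0.159). DHPS, which encodes the enzyme of the other step of hypusine synthesis, rose (0.66 ± 0.15, adjusted p = 0.00422). EIF5A2, a paralog of EIF5A, fell (-0.47 ± 0.12, adjusted p = 0.00909), as did the ATF4 transcript (-0.50 ± 0.12, adjusted p = 0.00677). Both calls ended without the first DOHH library (-0.44 and -0.47) and without the second (-0.48 and -0.52), though the changes hardly moved. They also ended without a scaling factor (-0.25, adjusted p = 0.135, and -0.29, adjusted p = 0.0785). MYC (0.31 ± 0.12, adjusted p = 0.0619) and CDKN1A (0.25 ± 0.15, adjusted p = 0.196) were not called, but were without the second non-targeting library (0.35 and 0.48, adjusted p = 0.0147 and 0.00173) and without a scaling factor (0.52 and 0.46, adjusted p = 0.011 and 0.049).

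Of the 31 proteasome genes 27 rose and none fell (27 and 0 adjusted over the list alone, median 0.85), including PSMB3 (1.46 ± 0.16) and PSMC1 (1.35 ± 0.12). Of 28 cytosolic heat shock chaperones 16 rose and 2 fell (17 and 2 adjusted over the list alone, median 0.54), with CCT2 at 0.85 ± 0.14. The inducible genes HSPA1B (1.77 ± 0.15) and HSPA1A (1.57 ± 0.20) are near-identical copies whose counts share reads. The proteasome had camera adjusted p = 2.27e-09 and chaperones 9.65e-04, and adjusted p = 0.66 with an estimated correlation for each. Of 38 lysosome and autophagy genes 22 rose and 1 fell (23 and 2 adjusted over the list alone), and the median was 0.59, or 0.35 without the first non-targeting library. Of 29 unfolded protein response genes 15 rose and 1 fell (16 and 1 adjusted over the list alone, median 0.45), led by SEC24D (1.46 ± 0.15) and PDIA3 (1.31 ± 0.21). For the lysosome camera adjusted p was 2.28e-04 and 7.47e-04 for the unfolded protein response, and adjusted p = 0.66 with an estimated correlation for each.

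Of 33 interferon-stimulated genes 15 rose (16 adjusted over the list alone, median 0.51), including LGALS3BP (1.56 ± 0.20) and HERC5 (1.56 ± 0.22). Of 28 immediate early genes 13 rose (13 adjusted over the list alone), including JUN (1.41 ± 0.19) and IER2 (1.28 ± 0.16), and the median was 0.54, or 0.36 without the first DOHH library. Adjusted p from camera was 2.5e-05 for interferon-stimulated and 0.00229 for immediate early genes, and adjusted p = 0.66 with an estimated correlation for each. Of 20 NF-kB and inflammatory genes 9 rose and 1 fell (10 and 1 adjusted over the list alone, median 0.53), including ICAM1 (1.21 ± 0.18). The NF-kB list had camera adjusted p = 0.00542, and adjusted p = 0.66 with an estimated correlation. Its median was 0.28 without the first DOHH library and 0.90 without the first non-targeting library, and its call ended without the second non-targeting library (adjusted p = 0.0771). Of the 36 ATF4 targets 15 rose and 7 fell (16 and 8 adjusted over the list alone, median 0.30), and the list was not called (camera adjusted p = 0.127, or 0.0485 without the second DOHH library).

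Ribosomal protein genes share reads with many pseudogenes. Of 47 of the large subunit 16 fell and 1 rose (16 and 1 adjusted over the list alone, median -0.34), and of 31 of the small subunit 13 fell and none rose (13 and 0 adjusted over the list alone, median -0.33). Their camera adjusted p was 8.25e-04 and 0.00158, with adjusted p = 0.667 and adjusted p = 0.66 with an estimated correlation. Without a scaling factor the medians were -0.12 and -0.11 and without the first non-targeting library -0.14 and -0.19, and both lists were still called. RPL12 (-0.86 ± 0.17) and RPS20 (-0.76 ± 0.15) fell, but were not called without the first DOHH library (adjusted p = 0.0575 and 0.055), while RPL3 rose (0.77 ± 0.13). Of 23 snoRNA host and translation-sensitive long noncoding RNAs 14 fell and 1 rose (14 and 1 adjusted over the list alone, median -0.54), including EPB41L4A-AS1 (-1.09 ± 0.13). Of 23 tRNA synthetases 13 rose and 1 fell (13 and 1 adjusted over the list alone, median 0.44), including HARS1 (1.00 ± 0.15). Of 19 nonsense-mediated decay factors 9 rose (9 adjusted over the list alone, median 0.28), including the helicase gene UPF1 (1.81 ± 0.19). The camera adjusted p was 2.13e-04, 0.00193 and 0.00229 for these 3 lists, and adjusted p = 0.66 with an estimated correlation for each.

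Of 64 ribosome biogenesis genes 24 rose and 3 fell (24 and 3 adjusted over the list alone), including NOC2L (1.62 ± 0.19). Their median was 0.18 (camera adjusted p = 0.00495, and adjusted p = 0.66 with an estimated correlation). It was 0.38 without the second non-targeting library, and the call ended without the first (0.11, adjusted p = 0.0763). Of 50 DNA replication genes 22 rose and 4 fell (22 and 4 adjusted over the list alone, median 0.35), including the polymerase gene POLD1 (1.55 ± 0.17) and CDC45 (1.36 ± 0.16). Replication genes had camera adjusted p = 0.00229, and adjusted p = 0.66 with an estimated correlation. Of 38 histone transcripts 11 rose and 1 fell (10 and 1 adjusted over the list alone, median 0.36). Histones had camera adjusted p = 0.00709, and adjusted p = 0.667 with an estimated correlation, and their call ended without the first non-targeting library (0.20, adjusted p = 0.203). Initiation factors were not called (18 of 44 rose and 7 fell, 19 and 8 adjusted over the list alone, camera adjusted p = 0.058), but were without the second non-targeting library (0.0482), with no low-count filter (0.0137) and with the GC and length offset (0.022). Nor were elongation and rescue factors (7 of 26 rose and 5 fell, 8 and 5 adjusted over the list alone, camera adjusted p = 0.54).

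All 13 mitochondrially encoded mRNAs fell (13 adjusted over the list alone, median -1.75), with a mean share of 1.19% against 4.09% in controls (camera adjusted p = 5.62e-06, and adjusted p = 0.66 with an estimated correlation). Of 396 small noncoding RNAs 249 fell and 5 rose. The nuclear-encoded respiratory chain had 22 of 73 genes higher and 7 lower (25 and 7 adjusted over the list alone, median 0.17), with NDUFV1 at 1.56 ± 0.21. Mitochondrial ribosomal protein genes had 26 of 75 higher and 9 lower (28 and 10 adjusted over the list alone, median 0.21), with MRPL28 at 1.51 ± 0.19. The camera adjusted p was 0.011 and 0.021, with adjusted p = 0.667 and adjusted p = 0.693 with an estimated correlation. Neither list was called without the first non-targeting library (0.11, adjusted p = 0.113, and 0.06, adjusted p = 0.35), and without the second the medians were 0.31 and 0.38. The mitochondrial ribosomal call also ended without the second DOHH library (adjusted p = 0.0629) and at a mean of at least 50 counts (0.0902).

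Hypoxia and glycolysis genes had 10 of 32 higher and 2 lower, the same adjusted over the list alone (median 0.31, camera adjusted p = 0.0234, and adjusted p = 0.667 with an estimated correlation). Their call ended without the second non-targeting library (adjusted p = 0.101) and at a mean of at least 50 counts (0.0528). Fibroblast markers had 3 of 5 higher (5 adjusted over the list alone, median 0.89, camera adjusted p = 0.0147, and adjusted p = 0.66 with an estimated correlation). Their median was 1.37 without the first non-targeting library, and the call ended without the second (adjusted p = 0.055). Of other markers, 1 of 4 endothelial genes, 3 of 3 embryonic kidney and neural genes and the 1 measured leukocyte gene rose, the same adjusted over the list alone (ITGAM, named after its value was seen, 1.05 ± 0.38). Not called were Wnt targets (3 of 15 rose and 1 fell, camera adjusted p = 0.127), epithelial-mesenchymal genes (6 of 23 rose, 0.161, or 0.035 without the first EIF5A library and 0.0337 with no low-count filter), cholesterol synthesis (8 of 28 rose and 2 fell, 0.417), p53 targets (9 of 30 rose and 4 fell, 0.351), mitosis (9 of 49 rose and 9 fell, 0.633) and differentiated intestinal genes (2 of 5 rose, 0.286), each the same adjusted over the list alone. Polyamine synthesis had 7 of 19 higher and 4 lower (7 and 5 adjusted over the list alone), with a median of -0.05, a mean of 0.19 and an upward test (camera adjusted p = 0.561). Collagens (9 of 27 rose and 5 fell, 10 and 5 adjusted over the list alone, camera adjusted p = 0.285) and NRF2 genes (8 of 24 rose and 5 fell, 9 and 5 adjusted over the list alone, 0.405) were not called.

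Without the first and the second DOHH library 2447 and 4003 transcripts were called, and 50.8% of all called transcripts rose. This share was 74.3% without a scaling factor, where the median of all genes moved by 0.21 and those of ribosome biogenesis, nonsense-mediated decay, snoRNA hosts, replication, histones, the respiratory chain, mitochondrial ribosomal proteins and hypoxia genes were 0.40, 0.49, -0.32, 0.56, 0.57, 0.39, 0.42 and 0.53, and 41.2% with the offset for GC content and length, where those of nonsense-mediated decay, mitochondrial ribosomal proteins, lysosome, NF-kB, immediate early and hypoxia genes were 0.16, 0.13, 0.33, 0.34, 0.34 and 0.16. With the offset the median of all genes was -0.09.

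**Figure D3:**
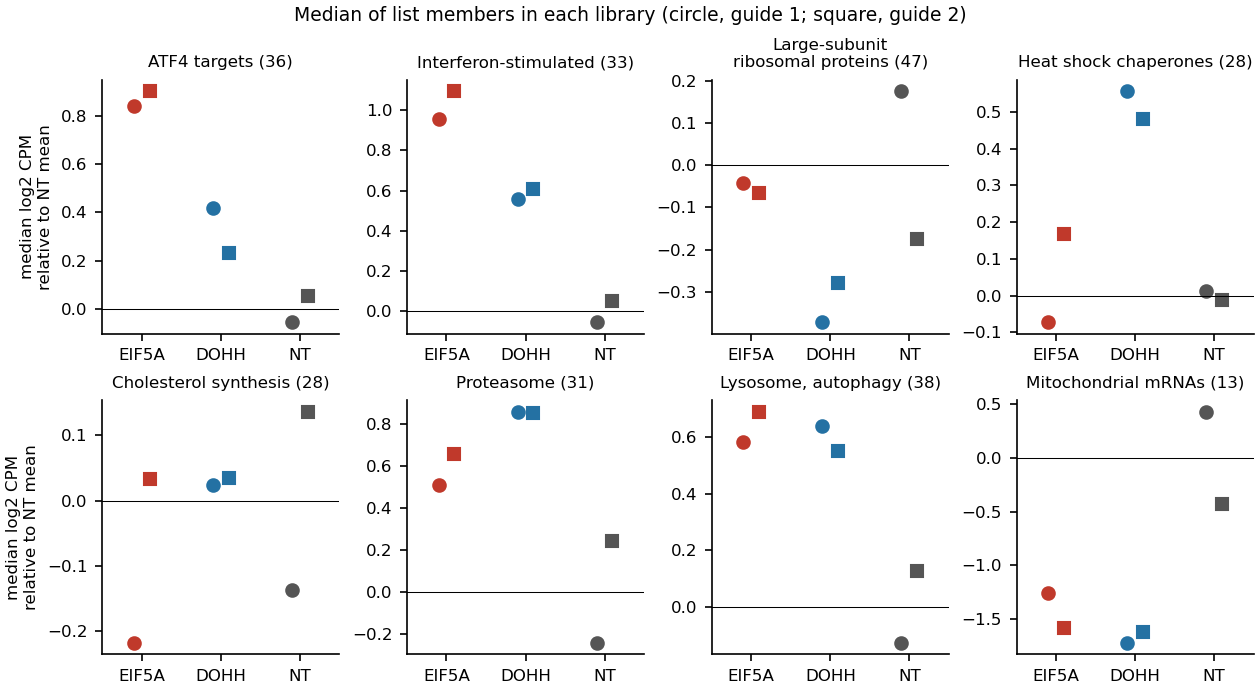
Median log2 CPM of the members of 8 gene lists in each of the 6 libraries (points), relative to the mean of the non-targeting (NT) libraries. ATF4 targets were higher in both EIF5A-targeted than in both DOHH-targeted libraries, and heat shock chaperones lower.

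The direct comparison of EIF5A with DOHH sgRNAs asks where targeting the factor and targeting its modifying enzyme differ. The non-targeting libraries entered it only through the filter, the scaling and the estimate of the spread. The ecto-nucleotidase gene NT5E was 2.96-fold higher in EIF5A-targeted cells (1.57 ± 0.12, adjusted p = 3.08e-04), having risen in these (0.82 ± 0.12) and fallen in DOHH-targeted cells (-0.75 ± 0.12) against controls. Higher too were the amino acid transporter gene SLC7A5 (1.38 ± 0.17, adjusted p = 0.00149), CHAC1 (1.41 ± 0.14, adjusted p = 5.48e-04) and SLC7A11 (1.34 ± 0.13, adjusted p = 4.17e-04). FUBP1 (-1.59 ± 0.14, adjusted p = 3.77e-04), the splicing factor gene SRSF11 (-1.46 ± 0.13, adjusted p = 3.77e-04) and HSPA1B (-1.52 ± 0.15, adjusted p = 4.39e-04) were lower. By camera with a preset correlation, ATF4 targets (18 of 36 higher), interferon-stimulated genes (6 of 33) and large and small subunit ribosomal proteins (1 of 47 and 0 of 31) were among the lists called higher with EIF5A sgRNAs. Chaperones (6 of 28 lower), cholesterol synthesis (9 of 28), proteasome (5 of 31) and DNA replication genes (2 of 50) were called lower, and for these 8 lists adjusted p = 0.666 to 0.992 with an estimated correlation.

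In all, 650 transcripts were higher and 525 lower in EIF5A-targeted cells (1175 of 17516), of which 112 and 113 differed at least 2-fold. Of the 1175, 194 had been called in both comparisons with controls, 438 with EIF5A sgRNAs alone, 410 with DOHH sgRNAs alone and 133 in neither. Under the rule for named genes, which asks for a mean log2 CPM of at least 3, the 5 largest rises were NT5E, IFI6, CHAC1, ARRDC4 and SLC7A5, and the 5 largest falls FUBP1, SNORA21, OBSL1, HSPA1B and SRSF11. SNORA21 (-1.54 ± 0.16) lies inside RPL23 on the same strand. IFI6 (1.46 ± 0.34, adjusted p = 0.0331) was not called without the second EIF5A library (0.76, adjusted p = 0.165), without either DOHH library (0.218 and 0.247) or without either non-targeting library (0.267 and 0.265). Its call also ended with only the 4 libraries of these groups (adjusted p = 0.239), with no low-count filter (0.127) and with DESeq2 (0.0644). EIF5A was lower with its own sgRNAs (-1.12 ± 0.13, adjusted p = 0.00132). The ATF4 transcript was higher (0.77 ± 0.12, adjusted p = 0.00539), and stayed at 0.74 to 0.79 without each EIF5A or DOHH library. With fewer libraries to estimate the spread it was then not called (adjusted p = 0.0789 and 0.0594 without the first or second EIF5A library, 0.16 and 0.0972 without the first or second DOHH library). CDKN1A was not called (0.53 ± 0.15, adjusted p = 0.0522), but was without either non-targeting library (2.71e-04 and 3.84e-04) and with the 4 libraries of these groups (8.37e-04). It was also called with the replicate block (0.53, adjusted p = 0.0381), no low-count filter (0.00613), a mean of at least 50 counts (0.0448), the GC and length offset (0.0169), DESeq2 (0.0183) and limma-voom (0.0493).

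Of 36 ATF4 targets 18 were higher with EIF5A sgRNAs and none lower (24 and 1 adjusted over the list alone, median 0.58), including DDIT3 (1.19 ± 0.15). Of 28 chaperones 6 were lower (18 adjusted over the list alone, median -0.48), including HSPA1A (-1.40 ± 0.19). Of 33 interferon-stimulated genes 6 were higher (17 higher and 2 lower adjusted over the list alone), such as OASL (0.93 ± 0.17), and the median was 0.44, or 0.27 without the second EIF5A library. Adjusted p from camera was 1.43e-10 for ATF4 targets, 1.18e-07 for chaperones and 4.51e-05 for interferon-stimulated genes, and adjusted p = 0.666 with an estimated correlation for each. Of 28 cholesterol synthesis genes 9 were lower (15 adjusted over the list alone, median -0.40), including LSS (-0.92 ± 0.18). Of 31 proteasome genes 5 were lower (13 adjusted over the list alone, median -0.36), including PSMD4 (-0.67 ± 0.14). The camera adjusted p was 4.19e-05 for cholesterol synthesis and 0.00115 for the proteasome, and adjusted p = 0.992 with an estimated correlation for each. Of 47 ribosomal protein genes of the large subunit RPL3 alone passed (0.55 ± 0.13, none adjusted over the list alone), and of 31 of the small subunit none did (none adjusted over the list alone). Both lists were called upward (medians 0.29 and 0.23, or 0.20 and 0.14 without a scaling factor, camera adjusted p = 1.14e-06 and 0.00115, and adjusted p = 0.992 with an estimated correlation for each). OASL, LSS, PSMD4 and RPL3 were not called without any 1 of the 4 compared libraries (adjusted p = 0.051 to 0.293).

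Further called lists depended on single libraries. DNA replication (2 of 50 lower, 2 adjusted over the list alone, median -0.23) was not called without the first EIF5A library (-0.15, adjusted p = 0.0971). Mitochondrial ribosomal proteins (3 of 75 lower, 2 adjusted over the list alone, median -0.16) were not called without the first EIF5A library (-0.09, adjusted p = 0.105), without the second DOHH library (0.216) or with the GC and length offset (0.0644). NF-kB genes (4 of 20 higher, 7 adjusted over the list alone) had a median of 0.26, or 0.46 and 0.49 without the second EIF5A and the first DOHH library. Immediate early genes (7 of 28 higher, 8 higher and 1 lower adjusted over the list alone), with KLF4 at 1.16 ± 0.14, had a median of 0.09, or 0.17 and 0.36 without these libraries, 0.03 with no low-count filter and 0.26 with the GC and length offset. The medians turned to -0.02 and -0.03 without the second DOHH library, where neither was called (adjusted p = 0.179 and 0.638), and immediate early genes were also not called without either non-targeting library (0.059 and 0.06). The camera adjusted p was 0.00108, 0.0209, 0.0116 and 0.0214 for these 4 lists, and adjusted p = 0.992 with an estimated correlation for each. Wnt targets (2 of 15 higher, 3 adjusted over the list alone, median 0.19) and epithelial-mesenchymal genes (6 of 23 higher, 8 adjusted over the list alone, median 0.11) had camera adjusted p = 0.0406 and 0.0178, with adjusted p = 0.666 and adjusted p = 0.975 with an estimated correlation. Neither was called without the second EIF5A library (0.118 and 0.199, the latter with a median of 0.16) or the second DOHH library (0.174 and 0.0713). The median of epithelial-mesenchymal genes was 0.25 and 0.22 without the first EIF5A and the first DOHH library and 0.19 with no low-count filter, and their call ended at a mean of at least 50 counts (0.06, adjusted p = 0.0684). The other 19 tested lists were not called, mitochondrially encoded mRNAs among them (none of 13 passed, none adjusted over the list alone, median 0.16, camera adjusted p = 0.481). Of these, histones, hypoxia genes and collagens were called higher without the first EIF5A library (0.41, 0.34 and 0.16, adjusted p = 0.00116, 1.92e-05 and 0.0152), collagens also without the first DOHH library (0.0166), and mitosis lower without the second EIF5A library (-0.14, adjusted p = 0.0273).

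Without the first or second EIF5A library 127 and 139 transcripts were called, without the first or second DOHH library 40 and 92, and without the first or second non-targeting library 3976 and 3882. Of 42 named genes called here 14 were called under every alternative in which they were tested (ARRDC4, CHAC1, DDIT3, EIF5A, FUBP1, HSPA1A, HSPA1B, KLF4, NT5E, OBSL1, SLC7A11, SLC7A5, SNORA21 and SRSF11). SNORA21 was not tested with small noncoding RNAs left out. In all, 55.3% of called transcripts were higher, against 31.5% without a scaling factor, where the medians of mitochondrial ribosomal proteins, NF-kB, immediate early, Wnt and epithelial-mesenchymal genes were -0.24, 0.17, 0.00, 0.10 and 0.02.

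The mean of both targeted groups was also set against the controls, since EIF5A and DOHH act in the same modification pathway. BAG1 (-2.29 ± 0.11, adjusted p = 5.32e-07) and the tRNA exporter gene XPOT (-1.13 ± 0.11, adjusted p = 2.77e-05) fell. CXXC1 (2.74 ± 0.12, adjusted p = 3.32e-07) and PSMC1 (1.13 ± 0.11, adjusted p = 3.29e-05) rose. In all 3866 transcripts rose and 3822 fell (7688 of 17516), and 50.3% of them rose, against 69.0% without a scaling factor and 40.1% with the GC and length offset. Of 32 tested lists 23 were called, 15 of them under every alternative of scaling, filter and left-out library. By camera with an estimated correlation 0 of the 32 lists were called. The proteasome (23 of 31 rose, 28 adjusted over the list alone, median 0.71) and interferon-stimulated genes (24 of 33 rose, 27 adjusted over the list alone, median 0.76) had camera adjusted p = 5.28e-08 each, and adjusted p = 0.604 with an estimated correlation. Mitochondrially encoded mRNAs (13 of 13 fell, 13 adjusted over the list alone, median -1.62) and snoRNA hosts (18 of 23 fell, 18 adjusted over the list alone, median -0.51, or -0.32 without the first non-targeting library) were lower. Their camera adjusted p was 4.87e-06 and 7.91e-05, and adjusted p = 0.604 with an estimated correlation for each.

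Ribosomal proteins of the large subunit (12 of 47 fell and 2 rose, 8 and 2 adjusted over the list alone) and of the small subunit (9 of 31 fell, 9 adjusted over the list alone) were called lower in the mean of both groups, each with a median of -0.22. Their camera adjusted p was 0.0344 and 0.0193, with adjusted p = 0.727 and adjusted p = 0.699 with an estimated correlation. Neither was called without the first non-targeting library (-0.03 and -0.08, adjusted p = 0.9 and 0.211), without the first DOHH library (0.105 and 0.0632) or without a scaling factor (-0.04 and -0.04, adjusted p = 0.154 and 0.0804), and without the second non-targeting library the medians were -0.40 and -0.38. The call of the large subunit also ended without the first or second EIF5A library (0.0523 and 0.0745) and with the GC and length offset (0.0778).

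The EIF5A and DOHH responses were compared across genes. Their log2 fold changes correlated at r = 0.805 over 17516 transcripts, which are not independent replicates. In 50 simulations of unchanged groups that shared the same controls the mean was 0.550 (0.531 to 0.570). The covariance was 0.393 against a simulated 0.0443, a difference of 0.349. The simulations gave all groups the same spread per gene, while the controls varied most, so the shared controls may add more than simulated. The sign was shared by 80.8% of transcripts against 67.5%, and 4383 transcripts, BAG1 and CXXC1 among them, were called in the same direction in both against a simulated mean of 0.04. Of these 2221 were higher and 2162 lower, where independent lists of the observed lengths would share 661 and 600. Another 19 were called in opposite directions, among them NT5E, where independent lists would share 1260. With 1 non-targeting library for each response, an alternative chosen after the data were seen, r was 0.674 and 0.602. The covariance of differences in log2 CPM was then 0.306 and 0.287. The simulations leave out real effects and the independent lists leave out the shared controls, so the overlap is not evidence of a shared effect by either. The controls were too few to split with 2 in each part, so part of the excess may come from the shared controls.

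**Figure D4:**
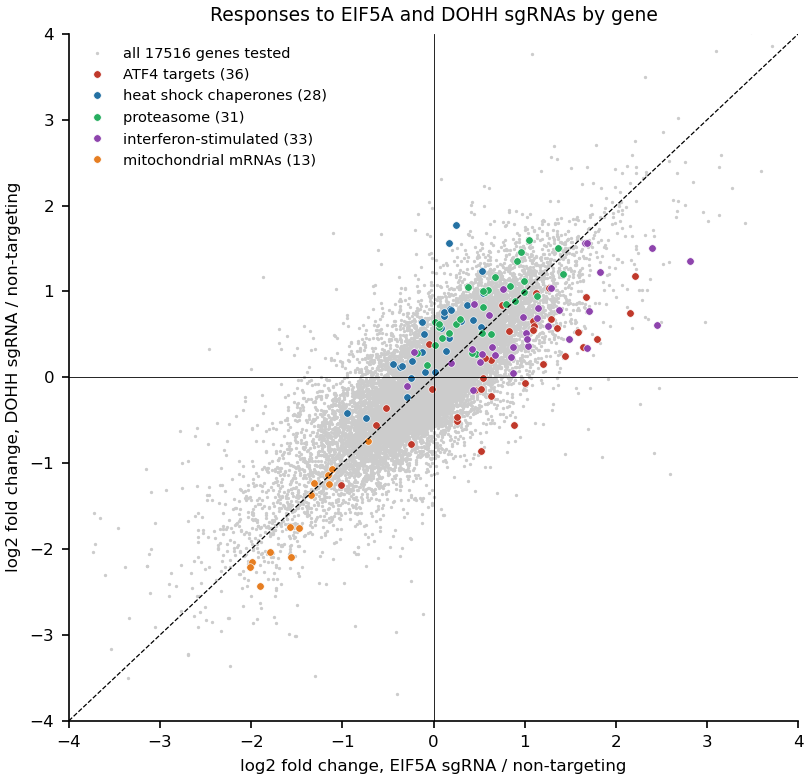
Log2 fold change of each tested transcript (points) with EIF5A sgRNAs (x axis) and DOHH sgRNAs (y axis) against the same non-targeting libraries, with 5 gene lists in colour and 8 transcripts outside the axes. The changes correlated at 0.805, with mitochondrial mRNAs low for both targets, ATF4 targets mostly below the line of equal change and chaperones mostly above it.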

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

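Of the tests below, those of the scaling, of the first non-targeting library alone, of a fall confined to mitochondrial transcripts, of the axis along which the non-targeting libraries vary and of a higher ATF4 mRNA level were chosen only after the result was seen. Each value in this part that compares EIF5A with DOHH was singled out because the difference between both targeted groups was itself tested and passed at adjusted p under 0.05. The values are log2 differences, EIF5A minus DOHH, with 2 libraries in each group.

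Among lists, the median difference was 0.575 for ATF4 targets, 0.444 for interferon-stimulated genes, 0.291 for ribosomal proteins of the large subunit, 0.228 for those of the small subunit, 0.260 for NF-kB genes, 0.194 for Wnt targets, 0.108 for epithelial-mesenchymal genes and 0.0921 for immediate early genes. It was -0.478 for heat shock chaperones, -0.403 for cholesterol synthesis, -0.359 for the proteasome, -0.230 for DNA replication and -0.156 for mitochondrial ribosomal proteins. None of these lists passed with an estimated correlation (camera, 0 of 32 lists, 1 at an unadjusted p under 0.05, and fry 0, 4 unadjusted). Without the second DOHH library 8 lists were called in place of 13, and NF-kB and immediate early genes then had medians of -0.02 and -0.03.

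Among genes, the difference was 1.57 for NT5E, 1.46 for IFI6, 1.41 for CHAC1, 1.39 for ARRDC4, 1.38 for SLC7A5, 1.27 for BIRC3, 1.08 for CXXC1, 0.95 for WWC3 and 0.77 for ATF4. It was -1.59 for FUBP1, -1.54 for SNORA21, -1.54 for OBSL1, -1.52 for HSPA1B, -1.46 for SRSF11, -1.12 for EIF5A, -0.75 for KIAA1191 and -0.72 for CAV2. The call of BIRC3 ended without the first EIF5A library (0.86), the first or second DOHH library (1.27 and 1.26) and the first non-targeting library (1.27). The calls of NT5E, CHAC1, ARRDC4, SLC7A5, FUBP1, SNORA21, OBSL1, HSPA1B, SRSF11 and EIF5A held without each of the 6 libraries and under the other alternatives in which they were tested, which for SNORA21 do not include leaving out small noncoding RNAs. Of the 42 named genes called in this comparison, 27 lost the call without the first DOHH library, 27 without the second, 23 without the first EIF5A library and 23 without the second.

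The difference of ATF4 targets between both targeted groups was weighed first. GC content and transcript length were argued against, since the median stayed at 0.578 with an offset for them, and so was a single library, since the lowest median without any 1 of the 4 libraries was 0.556. Across 10126 genes the difference between both targeted groups had a rank correlation of -0.255 with GC content and 0.204 with length. Other lists in this comparison may therefore be affected, though with the offset 12 were called in place of 13. Mitochondrial ribosomal proteins lost the call (camera adjusted p = 0.0644), and the median of immediate early genes was 0.26 in place of 0.09. The ATF4 transcript was itself higher with EIF5A sgRNAs, by 0.77, so a higher level of ATF4 mRNA is a candidate explanation, found and tested on the same data. Values against controls do not follow it, as ATF4 mRNA was not called with EIF5A sgRNAs (0.26, adjusted p = 0.11) where its targets had a median of 0.85, and fell with DOHH sgRNAs (-0.50) where they had a median of 0.30. These values share the controls that stood apart, and a shift common to both targeted groups would cancel in the difference between them. They therefore do not decide, and the explanation stays open. ATF4 is itself a member of the list. Without each of the 4 libraries the difference of the ATF4 transcript stayed at 0.74 to 0.79, while its call ended with fewer libraries to estimate the spread. A difference between EIF5A and DOHH targeting in depth of depletion or in the cells' stress state stays open, as protein levels were not measured in the data used here.

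The second pattern was that both non-targeting libraries stood apart, in mitochondrial and small noncoding RNA and in many other genes. A distortion of scaling by a few abundant RNAs would shift all other genes alike. As the whole cause of the calls between EIF5A and controls it was argued against, since with mitochondrial and small noncoding RNAs set aside 4102 transcripts rose and 1910 fell (31.8%) without a scaling factor. A planned test on the number of calls was set aside, as that number hardly moved with the scaling (6269 without a factor, 6533 with TMM), though the share that rose did (65.6% and 51.6%). For DOHH the test of directions was not run. Without a scaling factor 74.3% of its 6937 called transcripts rose, with no RNA class set aside. GC content and length as the whole cause of the mitochondrial fall were argued against (median -1.64 with the offset), as were the first non-targeting library alone (-1.08 without it, against -1.62) and a fall confined to mitochondrial transcripts, since the median of small noncoding RNAs encoded in the nucleus was -1.14. The difference between the non-targeting libraries correlated at 0.233 over 9185 genes with that between the second of them and the targeted libraries, so variation that also separates the controls, such as RNA handling or growth state, may contribute to the changes against controls. Library batch and the effect of targeting cannot be told apart here, since the labels give no batch and all non-targeting libraries lie on the same side.

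The third pattern was the number of large changes against controls, set against the counting of reads on a single transcript model per gene, if they were so counted. Of 1368 protein-coding genes counted on a model shorter than 0.5 of their longest transcript, 5.19% were called with at least a 2-fold change, against 8.16% of genes of matched expression among 11585 others. The ratio of 0.636 argues against short models as a source of the large changes as a set. Single genes may still be affected, such as CAV2, counted on 26.0% of its longest transcript.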

How the results depend on the processing

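The alternatives chosen only after the data were seen were the offset for GC content and length, leaving out mitochondrial and small noncoding RNAs, and separate controls for each response. No tested direction reversed under any alternative where the value was called with or without it. Changes of sign between values that were both not called were not counted as reversals. The medians of NF-kB and immediate early genes between EIF5A and DOHH turned negative without the second DOHH library. Those of ribosomal proteins with EIF5A sgRNAs turned positive without a scaling factor. Of the alternative values for named genes 4144 kept their side of the threshold, 65 gained a call and 166 lost it. For lists 1698 kept it, 32 gained a call and 178 lost it, 127 of the lost with an estimated correlation or fry. With at least a 2-fold change required, 2039 transcripts were called for EIF5A, 1910 for DOHH, 225 for EIF5A against DOHH and 1812 for both targeted groups, which follows from the added minimum. Between EIF5A and DOHH 1943 transcripts were called with no low-count filter, 3871 with only the 4 libraries of these groups, which leaves the wider spread of the controls out of the estimate, 1528 with DESeq2 and 1202 with limma-voom. The cause of the first was not tested. Against controls, the fits of only the 4 compared libraries called 5242 transcripts (EIF5A) and 6102 (DOHH), in place of 6533 and 6761. Without each library in turn the counts ranged from 3240 to 8068 (EIF5A), 2447 to 8274 (DOHH), 40 to 3976 (EIF5A against DOHH) and 5272 to 8696 (both groups). Where a group kept a single library, that library was assumed to vary like the others. Leaving out either non-targeting library, the group with the widest spread, raised the count between EIF5A and DOHH (3976 and 3882), and leaving out a targeted library lowered it. Camera with an estimated correlation called 0 lists for EIF5A (3 at an unadjusted p under 0.05), 0 for DOHH (0 unadjusted), 0 between them (1 unadjusted) and 0 for both groups (1 unadjusted), with 3 degrees of freedom against the preset camera's 20, 20, 13 and 23 calls. The estimated correlation was 0.949 for mitochondrially encoded mRNAs, 0.784 for the proteasome and 0.726 and 0.561 for large and small subunit ribosomal proteins. It was 0.0788 for ATF4 targets, 0.0768 for interferon-stimulated genes and -0.0164 for Wnt targets. Where it lies far above the preset 0.01, the preset camera's p-values can be far too small. Few degrees of freedom may then not be the only reason that calls were lost. Fry called 11 for EIF5A (18 unadjusted), 0 for DOHH (14 unadjusted), 0 between them (4 unadjusted) and 16 for both groups, and in its mixed form 31, 31, 16 and 32. Without each library in turn 8 to 14 lists were called between EIF5A and DOHH. The correlation of both responses ranged from 0.730 to 0.854 without each library, and was 0.674 and 0.602 with separate controls, which removes the shared libraries and leaves a single control for each. A difference common to both non-targeting libraries still enters both responses. The replicate block, with the guide number added to the design, gave 6674, 6862, 1463 and 7775 transcripts, though guide numbers did not pair the libraries (correlations of guide differences between groups of -0.05, 0.12 and -0.04). Low counts limited the tests to 17516 transcripts, against 33785 with no low-count filter.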

Other observations

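Of the tests in this part none was chosen after its result was seen, but the genes named in the next 2 paragraphs were chosen after their values were seen and were not run under the alternatives. In the list of polyamine synthesis, whose product spermidine is the donor for hypusine, and of hypusination, 5 of 19 genes rose and 5 fell with EIF5A sgRNAs and 7 rose and 4 fell with DOHH sgRNAs, and the list was not called (camera adjusted p = 0.557 and 0.561). It also holds EIF5A, EIF5A2, DHPS and DOHH, and the targeted gene EIF5A is among the 5 that fell with EIF5A sgRNAs. SAT1, which encodes the acetylase that starts polyamine breakdown, rose with EIF5A (1.08 ± 0.13, adjusted p = 1.22e-04) and DOHH sgRNAs (0.92 ± 0.13, adjusted p = 3.26e-04). AZIN1, whose product relieves inhibition of ornithine decarboxylase, also rose (1.06 ± 0.14 and 1.25 ± 0.14), as did ARG2, an arginase gene (1.89 ± 0.17 in EIF5A). The synthesis genes AMD1 (-0.69 ± 0.14 and -0.93 ± 0.14), SRM (-0.69 ± 0.12 and -0.63 ± 0.12) and SMS (-0.45 ± 0.12 and -0.34 ± 0.12) fell with EIF5A and DOHH sgRNAs. ODC1 was not called (0.19 ± 0.14 and -0.15 ± 0.14, adjusted p = 0.304 and 0.408). The non-targeting libraries that stood apart are the controls of all these values.

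Of 26 genes of elongation, termination and ribosome rescue 7 rose and 1 fell with EIF5A sgRNAs and 7 rose and 5 fell with DOHH sgRNAs, and the list was not called (camera adjusted p = 0.508 and 0.54). Among its members, PELO (1.14 ± 0.14 and 0.63 ± 0.14) and its partner HBS1L (0.87 ± 0.13 and 0.67 ± 0.13) rose with EIF5A and DOHH sgRNAs, as did EDF1 (0.76 ± 0.12 and 0.56 ± 0.12) and GTPBP1 (0.64 ± 0.13 and 0.57 ± 0.13). EEF2K fell with both (-0.61 ± 0.15 and -0.65 ± 0.15), and EEF1A1 (-0.85 ± 0.19), EEF2 (-0.81 ± 0.18), RACK1 (-0.51 ± 0.17) and LTN1 (-0.44 ± 0.14) fell with DOHH sgRNAs. PELO was also higher with EIF5A than with DOHH sgRNAs (0.51 ± 0.14, adjusted p = 0.0483), and GSPT1 was lower (-0.79 ± 0.13, adjusted p = 0.00705). Of 44 initiation and start codon factors 19 rose and 3 fell with EIF5A sgRNAs (camera adjusted p = 0.00757, and adjusted p = 0.606 with an estimated correlation) and 18 rose and 7 fell with DOHH sgRNAs (camera adjusted p = 0.058). Among these, EIF1 (0.93 ± 0.14 and 0.66 ± 0.14), EIF1B (0.82 ± 0.14 and 0.45 ± 0.14) and EIF1AX (0.68 ± 0.15 and 0.43 ± 0.15) rose, and EIF5, whose product opposes that of EIF1, fell (-0.72 ± 0.13 and -0.51 ± 0.13). None of these start codon genes differed detectably between EIF5A and DOHH sgRNAs (adjusted p = 0.12 to 0.358).

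A hypothesis was that mRNAs encoding 3 prolines in a row, at which eIF5A acts, fall when EIF5A is targeted. The median change of 2934 such genes was 0.13 against 0.15 in sets matched on expression, GC content and coding length from 7990 others, a difference of -0.0170, and 45 of 1000 sets lay at or below it. The difference was -0.0348 with DOHH sgRNAs (4 of 1000 sets) and -0.0112 for the mean of both (141 of 1000), and between EIF5A and DOHH it was 0.0168, with 982 of 1000 sets at or below. The motif genes did not fall with EIF5A sgRNAs, as their median change was positive, and lay only slightly below the matched genes. The sets redraw matched genes with the fold changes held fixed, so their counts carry no spread between libraries. The shift is small and the motif genes were not lower with EIF5A than with DOHH sgRNAs.

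A further hypothesis was that a Cas9 break could cost the arm end distal to it. The 88 genes distal to EIF5A on chromosome 17 had a median difference, EIF5A minus DOHH, of -0.0827, and 9.31% of 8342 runs of as many neighbouring genes elsewhere lay below it, which left a loss in part of the cells undecided. The 78 genes distal to DOHH on chromosome 19 had a median of -0.00566 where a loss with DOHH sgRNAs would raise it, with 30.6% of 8505 runs below, which argues against a loss large enough to see by this measure.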
